A study of Drosophila carrolli and Drosophila prolongata and Drosophila melanogaster with 113 samples.

How the data were processed

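RNA was measured by sequencing in larval leg imaginal discs, the epithelial sacs that form the adult legs, of 3 fly species. The labels describe 113 samples in 24 groups: 3 species by sex, by foreleg or midleg disc, and by an early or a late time. The series design text names 20 and 8 hours before wandering, the stage at which larvae leave the food, and the sample labels say early or late without hours. Early was taken as 20 hours and late as 8 hours because of their order in time. Per the labels, RNA was purified on Qiagen RNeasy mini columns and libraries were made with an NEB stranded mRNA kit. A total of 108 libraries were used. Of the 6 samples without a count table of their own, 4 were not analysed here, and 2 share 1 title and 1 table, which entered as a single unnumbered library of carrolli male midleg early. The 4 are also male midlegs: prolongata late replicate 2, carrolli early replicate 6 and late replicate 2, and melanogaster early replicate 3. The loss thus fell on male midlegs alone. Nothing in the labels says that libraries of a group came from separate larvae, pools or cultures, so the p-values measure the spread between these samples, which may be technical.

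Each deposited table holds the authors' raw read counts per gene for 1 library, with 1 column read without regard to strand and 1 column for each strand. The submitters' processing notes name the aligner STAR without a version. The genome builds and annotations are not given in the sources used here, so no coordinates are given. The deposited tables list genes by Drosophila melanogaster symbol, or by another name where no symbol was assigned, and carry no other identifier. They hold 19440 genes for prolongata, 16327 for carrolli and 17609 for melanogaster. The column of the sense strand was used. The antisense column held 2.83% of the strand-assigned gene reads in prolongata, 2.77% in carrolli and 3.26% in melanogaster. Read totals that name no gene were left out of library sizes and tests and made up 10.5% to 25.2% of each library's reads. Reads assigned to genes ranged from 33297387 to 60551946 per library. Chromosome X membership was taken from the BDGP6.54 annotation of D. melanogaster by gene symbol, in all species. Genes that share reads with a near-identical copy could be miscounted by any such counting, and how the authors treated such reads beyond their unique assignment is not given in the sources used here.

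Each species was fitted alone, since each was counted against its own gene list, with 1 mean per group and no covariate. edgeR 4.0.16 in R 4.3.3 was used with filterByExpr (minimum count 10), TMM normalisation, the quasi-likelihood test (estimateDisp, glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment over all genes tested. Genes were called at an adjusted p of 0.05. The fits tested 10893 genes in 36 prolongata libraries, 10010 in 37 carrolli libraries and 10706 in 35 melanogaster libraries, with 28, 29 and 27 residual degrees of freedom. A joint fit of the 108 libraries tested 9501 genes present in all 3 tables, and compared the prolongata contrast with the mean of the same contrast in the other 2 species. Sex contrasts (male minus female) within a leg, leg contrasts (foreleg minus midleg) within a sex, and their interaction were averaged over the 2 stages. The stage contrast (late minus early) was averaged over sex and leg. For prolongata forelegs the sex contrast was also taken at each stage. Every adjusted p quoted for a gene is from these edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, and every fold change is log2 with its standard error. That error was derived from the test, as the absolute log2 change divided by the square root of its F statistic. Levels are CPM, a gene's count scaled to a common TMM-adjusted library size, as mean ± SD.

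Lists of genes were fixed as pathways, patterning systems, cell functions and markers of other tissues. Of 28 lists, 26 had at least 5 tested members in some comparison, which gave 581 list tests. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. With the preset correlation 187 of the 581 tests passed. With an estimated correlation 4 passed: trachea and Hox genes between the legs of prolongata females, Hox genes between the legs of carrolli females, and sex determination genes between the sexes in melanogaster midlegs. Counts "adjusted over the list alone" use Benjamini-Hochberg within the list's members. fry, which asks whether members move on balance one way without comparing them to other genes, passed for 92 tests.

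Genes were named by rule: 10 genes in every comparison whatever their test (dsx, tra, roX1, roX2, Scr, Antp, Ubx, InR, Dll and dac), then up to 4 called members per list by adjusted p, then called genes at a mean of at least 5 CPM among the 8 with the largest fold in each direction. Up to 30 genes were named in a main comparison and up to 12 in others. Genes outside this rule are said to have been chosen after their values were seen. The groups, contrasts, tests, lists, naming rule and the first set of alternatives were fixed before the data were examined. These alternatives were DESeq2 1.42.0, RLE normalisation, no low-count filter, unstranded counts, the replicate number as a block, each library left out in turn, and the 2 other list tests.

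Added after seeing the data were 3 further alternatives. The first left out libraries labelled female in which roX1, an RNA of the male dosage compensation complex, lay above 5% of the male mean of the same species, leg and stage. The second left out libraries with the neuronal gene nSyb above 3 times the species median. The third added as a covariate a score of developmental stage, the mean log2(CPM + 0.5) of genes higher late in both other species minus that of genes lower late in both. Pairs of libraries within a group were checked for duplicates by a chi-square test over genes. The smallest chi-square per degree of freedom was 15.9 in prolongata, 16.4 in carrolli and 24.4 in melanogaster, so no pair agreed within sampling noise.

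The scripts were tested on simulated counts drawn from the means, spread and library sizes of the real samples, with known changes in 200 genes, of which those past the filter were scored (195 in prolongata forelegs). In the prolongata foreleg sex contrast 68.4% of simulated 2-fold and 55.7% of 1.5-fold changes were called, with 6 false calls among 10756 genes that passed the filter. In the prolongata interaction these shares were 55.1% and 35.1%, with 5 false calls. In the carrolli and melanogaster foreleg sex contrasts 79.6% and 63.3% of 2-fold changes were called, and in the joint contrast 75.0%. A changed list was called by camera in each of 8 simulated contrasts, with 0 calls of random lists. fry called 1 random list in the carrolli stage contrast and 2 in the joint contrast. The simulated genes were drawn independently of each other, so these counts do not bear on false list calls where genes vary together.

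Stage cannot be separated from the order of the serial numbers in the labels, which run from 1 to 60 for early and from 63 to 132 for late libraries. Whether these numbers give the order of library preparation is not stated. In early carrolli and melanogaster libraries males mostly hold lower serial numbers than females, as do prolongata males against some females. Sex contrasts at the early stage are therefore not free of this order. Other splits of the same libraries were also tested, 100 per contrast and 40 for the joint fit.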

Results

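Gene expression was measured by RNA sequencing in foreleg and midleg imaginal discs of Drosophila prolongata, a fly whose males carry enlarged forelegs used in fights and displays, and of its relatives D. carrolli and D. melanogaster. Discs of both sexes were taken at an early and a late time before wandering. In prolongata the 8 groups held, in the order female foreleg, male foreleg, female midleg and male midleg, 5, 4, 5 and 3 early libraries and 5, 5, 5 and 4 late libraries. The same groups held 5, 5, 5, 3, 5, 5, 5 and 4 libraries in carrolli and 4, 4, 4, 4, 4, 5, 5 and 5 in melanogaster. Reads assigned to genes ranged from 33297387 to 54857170 per library in prolongata, from 36471132 to 55881694 in carrolli and from 36788055 to 60551946 in melanogaster.

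The sex labels were compared with roX1, a non-coding RNA of the complex that raises X-linked transcription in males. Libraries labelled male held 1016 to 2116 CPM in prolongata, 1074 to 1906 CPM in carrolli and 766 to 1116 CPM in melanogaster. The median in libraries labelled female was 0.342, 0.220 and 5.17 CPM in the same order. Of the libraries labelled female, 4 in prolongata, 6 in carrolli and 2 in melanogaster lay above 5% of the male mean of the same species, leg and stage. The carrolli library labelled female midleg early replicate 1 reached 1434 CPM, 107% of the male mean. The next were prolongata female midleg late replicate 1 at 557 CPM and female foreleg late replicate 1 at 449 CPM. These 2 prolongata libraries also held the highest levels of the haemocyte gene Hml in the species, 1984 and 1249 CPM, against at most 529 CPM in any other. The neuronal vesicle gene nSyb had medians of 5.00, 2.69 and 3.93 CPM in the 3 species and exceeded 3 times its species median in 4, 5 and 2 libraries. The highest values were 61.4 CPM in carrolli female foreleg late replicate 4, 49.3 CPM in melanogaster male foreleg early replicate 4 and 40.7 CPM in carrolli female foreleg early replicate 1.

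**Figure D1:**
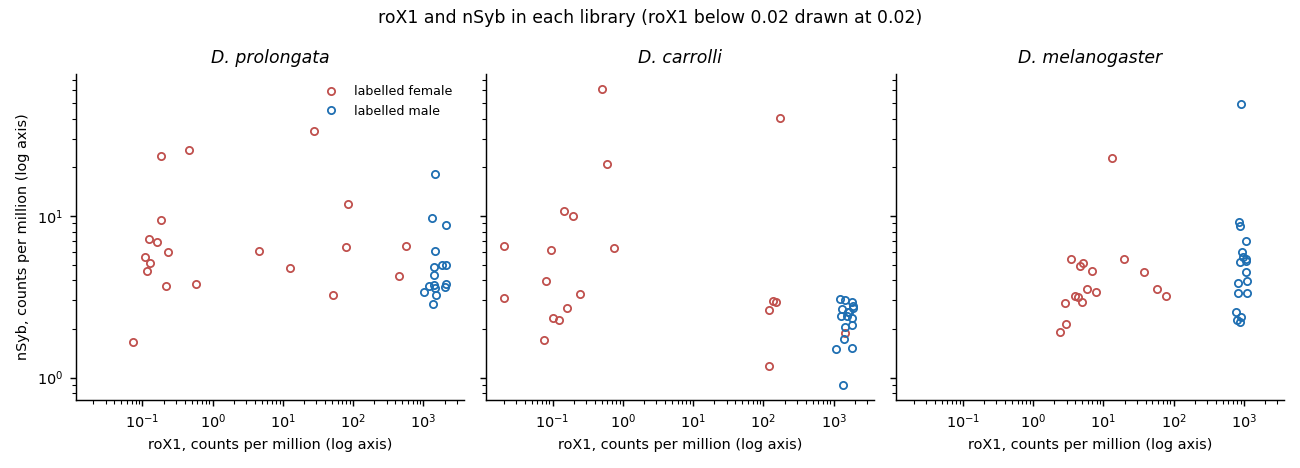
roX1 against nSyb, both in CPM on log axes, with each circle 1 library coloured by its labelled sex, for the 3 species. Libraries labelled male lie at 766 CPM of roX1 or above, and 1 carrolli library labelled female lies among them at 1434 CPM.

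The first question was how the male foreleg of prolongata, the enlarged leg, differed from the female foreleg. The sex determination gene dsx, the transcription factor that directs sexual differentiation of tissues, was lower in males, at 15.6 ± 4.01 CPM (SD, n = 9) against 80.1 ± 16.1 CPM in females (SD, n = 10), a log2 change of -2.39 ± 0.14 (SE). The Hox gene Scr, which specifies the first thoracic segment and the foreleg, was lower in males by a log2 change of -0.98 ± 0.20, at 228 ± 100 against 416 ± 133 CPM. Sxl, the master switch of female development, changed by -1.51 ± 0.12, and its target tra by -0.73 ± 0.11, while msl-2, a subunit of the dosage compensation complex, was higher by 0.71 ± 0.09. The insulin receptor InR changed by -0.59 ± 0.14, at 34.4 ± 9.94 against 49.2 ± 14.5 CPM. The adjusted p of these genes in the edgeR quasi-likelihood test ranged from 7.2e-13 for dsx to 0.0046 for InR. roX1 was higher in males by 5.30 ± 1.44 (adjusted p = 0.011, edgeR) and roX2, the other RNA of the complex, by 5.59 ± 1.02 (0.00044), and these became 8.70 and 8.95 without female foreleg early replicate 1.

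Most patterning genes that passed the test were lower in prolongata male forelegs. Of 31 tested genes of Hedgehog, Wingless and Dpp signalling, the systems that pattern the disc, 14 fell, 0 rose and 17 did not pass (19 fell when adjusted over the list alone). Among them were the Wingless receptor gene fz2 (-0.41 ± 0.08) and the T-box gene Doc2 (-0.65 ± 0.13). The list's adjusted p was 1.1e-08 by camera, and adjusted p = 0.30 with an estimated correlation. Of 25 proximodistal leg genes 10 fell and 1 rose (13 and 1 adjusted over the list alone). The zinc finger transcription factor gene Sp1 changed by -0.55 ± 0.09, the tarsal genes bab2 by -0.85 ± 0.16 and Lim1 by -0.45 ± 0.09, and dac, which specifies the intermediate leg, by -0.40 ± 0.11. Dll, which specifies the distal leg, did not pass at -0.13 ± 0.08 (adjusted p = 0.28, edgeR). The list's adjusted p was 9.0e-06 by camera, and adjusted p = 0.30 with an estimated correlation. Of 25 neural precursor genes 8 fell and 1 rose (12 and 1 adjusted over the list alone), with the proneural genes sc at -1.42 ± 0.23, ac at -1.09 ± 0.19 and sens at -1.03 ± 0.16. Its adjusted p was 2.9e-06 by camera, and adjusted p = 0.12 with an estimated correlation.

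Of 20 Hippo pathway genes, which restrain tissue growth, 5 fell and 0 rose (11 and 0 adjusted over the list alone), among them the apoptosis inhibitor and pathway target Diap1 at -0.64 ± 0.10. Its adjusted p was 1.8e-05 by camera, and adjusted p = 0.30 with an estimated correlation. The EGFR ligand vn changed by -0.66 ± 0.11, the ecdysone-induced transcription factor br by -0.86 ± 0.14, the serine protease Sb by -1.38 ± 0.25, the cell surface gene trn by -0.48 ± 0.09 and the vacuolar sorting gene dor by -0.26 ± 0.04. Of 27 insulin and TOR genes 2 fell and 0 rose (1 and 0 adjusted over the list alone; adjusted p = 0.77 by camera). Of 40 cell cycle genes 7 fell and 1 rose, in each case also when adjusted over the list alone (adjusted p = 0.72 by camera). In the other direction, 10 of 20 genes of mitochondrial respiration rose and 0 fell (16 and 0 adjusted over the list alone), including the respiratory complex gene ND-75 at 0.42 ± 0.07. The adjusted p was 3.1e-09 by camera, and adjusted p = 0.30 with an estimated correlation.

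Among markers of other tissues, 2 of 18 muscle genes rose and 1 fell, with the same counts adjusted over the list alone and a median log2 change of 0.51 (adjusted p = 0.12 by camera). Strn-Mlck changed by 0.45 ± 0.09 and the muscle transcription factor Mef2 by -0.33 ± 0.06. The muscle myosin gene Mhc spanned 10.7 to 1956 CPM in male and 8.43 to 682 CPM in female forelegs. Named after its values were seen, the haemocyte gene Hml spanned 247 to 462 CPM in early male and 19.6 to 223 CPM in early female forelegs. In late forelegs the ranges overlapped, at 49.1 to 251 CPM in males and 35.7 to 1249 CPM in females. Of 13 glial and central nervous genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), among them the glial receptor moody at 0.80 ± 0.14, while the list's median was -0.15 (adjusted p = 0.47 by camera, direction up). nSyb itself was -0.21 ± 0.40 (adjusted p = 0.78, edgeR). Of 16 genes of other imaginal discs 8 fell and 0 rose (10 and 0 adjusted over the list alone), with adjusted p = 1.1e-04 by camera, and adjusted p = 0.12 with an estimated correlation. Antp and Ubx, Hox genes of more posterior segments, did not pass at 0.44 ± 0.29 and 0.06 ± 0.47.

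In all, 756 genes were higher and 906 lower in male forelegs of prolongata (1662 of 10893 tested), with 185 and 201 past a 2-fold change. Outside the naming rule, and chosen after the values were seen, were the largest well-measured decreases. The activin antagonist gene Fs changed by -3.81 ± 0.34, from 60.8 ± 19.7 CPM in females to 4.46 ± 3.29 CPM in males, and CG10702 by -3.44 ± 0.24, from 127 ± 24 to 11.6 ± 6.56 CPM. Without the libraries labelled female with roX1 above 5% of the male mean the count was 2339, and without the libraries with high nSyb it was 1456. With the stage score as a covariate, chosen after seeing the data, it was 2802, of which 1644 were shared with the 1662. The replicate number as a block gave 3195.

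**Figure D2:**
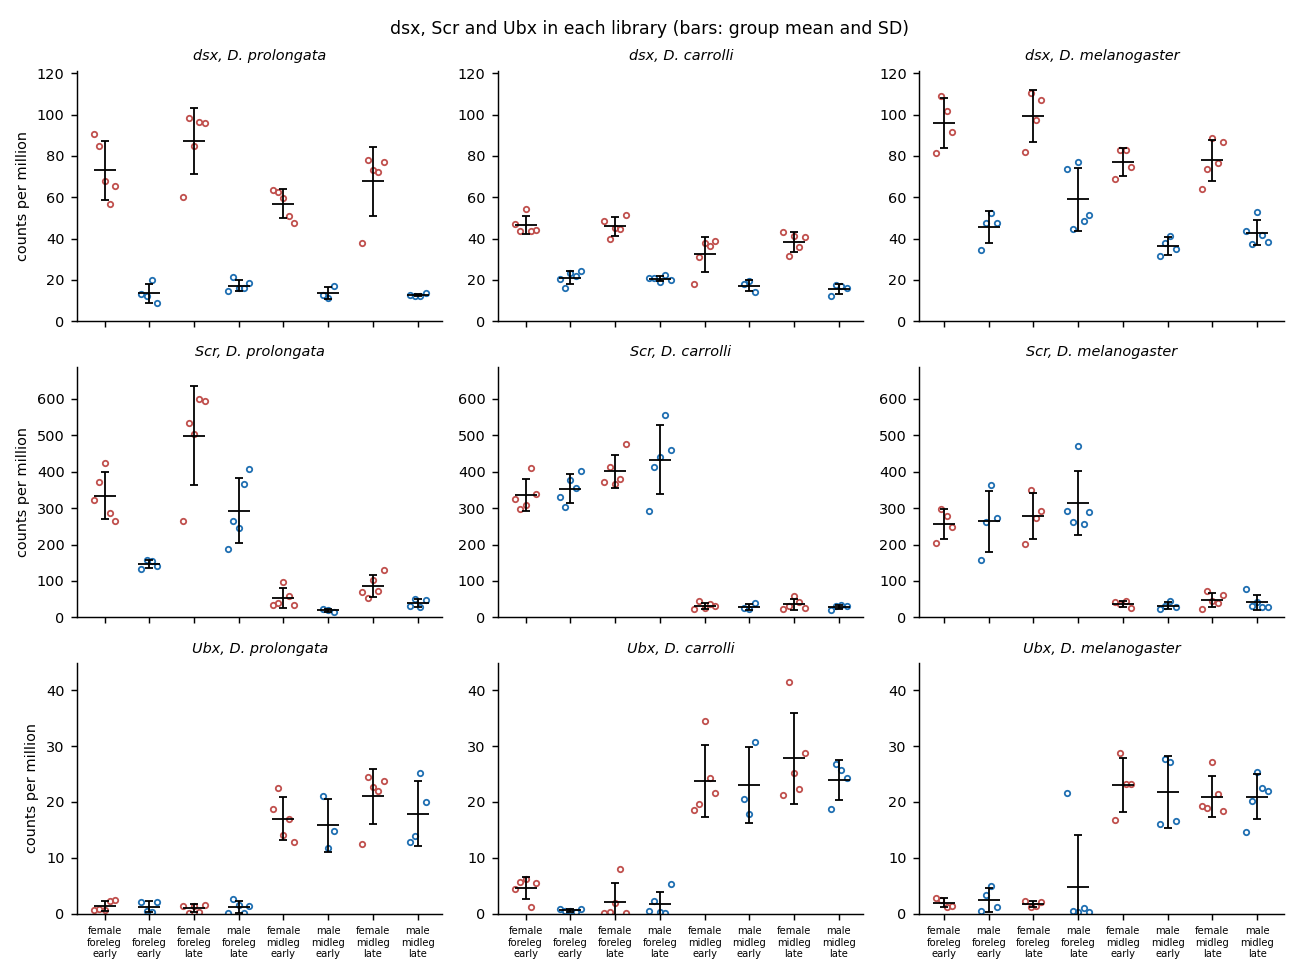
dsx, Scr and Ubx in CPM in each library (circles) with the group mean and SD (bars), by species, sex, leg and stage. dsx lies lower in males in each species, Scr lies lower in male than female forelegs of prolongata, and Ubx in melanogaster male foreleg late replicate 2 stands at 21.6 CPM, near the midleg level.

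The same genes were examined by stage in the prolongata foreleg. dsx was lower in males by -2.44 ± 0.21 early (4 male and 5 female libraries) and by -2.34 ± 0.19 late (5 and 5), and Sxl by -1.58 ± 0.17 and -1.43 ± 0.16. At the early stage vn changed by -0.92 ± 0.16, Scr by -1.19 ± 0.29, InR by -0.79 ± 0.21 and dac by -0.63 ± 0.16, all called. At the late stage Scr was -0.77 ± 0.27 (adjusted p = 0.15, edgeR), InR -0.39 ± 0.19 (0.32) and dac -0.17 ± 0.15 (0.62), none of which passed, and msl-2 was higher by 0.79 ± 0.13. The early comparison called 745 genes (325 higher, 420 lower) and the late one 174 (54 higher, 120 lower). The difference between the stages called 0 genes in edgeR, with 422 at an unadjusted p under 0.05, and 7 in DESeq2. In that test dsx differed by 0.11 ± 0.27, Scr by 0.42 ± 0.39, InR by 0.40 ± 0.28 and dac by 0.45 ± 0.22 (adjusted p = 1.00 each, edgeR).

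Single libraries moved the counts by stage. The early count was 489 without female foreleg early replicate 2, 338 without replicate 3 of that group, and 419, 359 and 339 without male foreleg early replicates 1, 2 and 4. The balance turned in the last of these fits, with 176 higher and 163 lower, and was near even at 180 and 179 without replicate 2. The other fits named kept more lower genes. The late count was 268 without female foreleg early replicate 3. It was 458, 81, 66, 74 and 72 without female foreleg late replicates 1 to 5 in turn, and 54, 61 and 64 without male foreleg late replicates 1, 3 and 4. Without the roX1 libraries the early and late counts were 1279 and 785, and without the nSyb libraries 383 and 147. Without a low-count filter the late count was 98, and in DESeq2 it was 464.

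The midleg, which is not enlarged in males, served as the comparison leg. In prolongata midlegs dsx was lower in males by -2.24 ± 0.16, at 13.1 ± 1.90 CPM (n = 7) against 62.3 ± 13.5 CPM (n = 10), Sxl by -1.47 ± 0.13, tra by -0.78 ± 0.12 and Scr by -1.27 ± 0.22. msl-2 was higher by 0.80 ± 0.10, roX1 by 4.96 ± 1.44 and roX2 by 5.40 ± 1.03. InR was -0.40 ± 0.15 (adjusted p = 0.093, edgeR), dac -0.25 ± 0.12 (0.18) and Dll -0.08 ± 0.09 (0.60), none of which passed, nor did Antp at 0.43 ± 0.31 and Ubx at -0.17 ± 0.47. Of 25 neural precursor genes 9 fell and 0 rose (13 and 0 adjusted over the list alone), with adjusted p = 5.7e-06 by camera, and adjusted p = 0.26 with an estimated correlation. Of 31 Hedgehog, Wingless and Dpp genes 3 fell (8 adjusted over the list alone), and of 20 respiration genes 1 rose (3 adjusted over the list alone). Their adjusted p was 1.8e-04 and 1.2e-04 by camera, and adjusted p = 0.55 with an estimated correlation for each. Of 18 muscle genes 2 rose in either adjustment (2 adjusted over the list alone), with adjusted p = 0.0016 by camera, and adjusted p = 0.55 with an estimated correlation. The midleg comparison called 992 genes, 433 higher and 559 lower. Of these, 276 higher and 419 lower genes were also called in the foreleg, against 30.1 and 46.5 expected of independent lists.

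The midleg count depended on the libraries used. It was 650 without female midleg early replicate 2, 1619 and 632 without female midleg late replicates 1 and 4, and 436 (278 higher, 158 lower) and 544 without male midleg early replicates 2 and 3. Without a low-count filter it was 746, of which 435 were higher and 311 lower. It rose to 2190 without the roX1 libraries and fell to 315 without the nSyb libraries, which include female midleg late replicates 3 and 4 at 25.8 and 33.5 CPM of nSyb.

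Whether the sex difference itself differed between the legs of prolongata was tested as an interaction. dsx gave -0.15 ± 0.20, Scr 0.29 ± 0.29, InR -0.19 ± 0.21, dac -0.15 ± 0.16, Dll -0.05 ± 0.12 and tra 0.05 ± 0.17, each with an adjusted p of 1.00 in edgeR. Of 20 respiration genes 0 passed, and 0 adjusted over the list alone, with a median of 0.12 (adjusted p = 8.7e-04 by camera, and adjusted p = 0.62 with an estimated correlation). Of 31 Hedgehog, Wingless and Dpp genes 0 passed, and 0 adjusted over the list alone, with a median of -0.07 (adjusted p = 0.0014 by camera, and adjusted p = 0.62 with an estimated correlation). No gene of the 10893 was called in edgeR, 197 had an unadjusted p under 0.05, and DESeq2 called 8. With the replicate number as a block edgeR called 1. The median standard error of the interaction was 0.18 on the log2 scale, against 0.12 for the foreleg sex contrast.

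The legs were then compared within each sex of prolongata. In males (9 foreleg and 7 midleg libraries) Scr was higher in the foreleg by 2.90 ± 0.24 and Ubx, the Hox gene of the third thoracic segment, lower by -3.83 ± 0.52. Of 11 Hox and segment identity genes 2 rose and 1 fell (3 and 1 adjusted over the list alone), the other that rose being the teashirt paralogue tio at 0.52 ± 0.11 (adjusted p = 0.0065 by camera, and adjusted p = 0.31 with an estimated correlation). The wing gene vg was lower by -1.67 ± 0.38. Also higher in the foreleg were CG5080 (2.51 ± 0.41), CG8483 (1.03 ± 0.11), CG4115 (0.82 ± 0.18), the neuropeptide gene natalisin (0.53 ± 0.10) and the zinc finger gene opa (0.38 ± 0.09). Lower were CG14893 (-6.49 ± 1.52), CG4382 (-4.18 ± 0.96), CG9449 (-2.70 ± 0.51), CG14258 (-2.51 ± 0.51), zye (-2.0 ± 0.44), CG13749 (-1.89 ± 0.43) and Ddc (-1.67 ± 0.32), which encodes dopa decarboxylase of the cuticle tanning pathway. dsx, InR, Dll and dac lay between 0.00 and 0.21 and did not pass.

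No member was called between the male legs of prolongata in the muscle list (18 genes, median -0.29; edgeR), with 1 fall adjusted over the list alone and adjusted p = 6.6e-06 by camera, and adjusted p = 0.62 with an estimated correlation. The haemocyte list (13 genes, median -0.47) had 0 called, and 0 adjusted over the list alone, with adjusted p = 1.9e-04 by camera, and adjusted p = 0.62 with an estimated correlation. The cell cycle list (40 genes, median 0.07) had 0 called in each way of adjusting, with adjusted p = 1.7e-04 by camera, and adjusted p = 0.62 with an estimated correlation. Mhc averaged 363 ± 610 CPM in male forelegs and 418 ± 317 CPM in male midlegs. The male comparison called 47 genes (10 higher, 37 lower). Without single libraries it called 22 and 28 (male foreleg early replicates 2 and 3), 29, 29, 25 and 28 (male foreleg late replicates 1, 3, 4 and 5), 27 and 25 (male midleg early replicates 2 and 3), and 31 and 30 (male midleg late replicates 4 and 5). It called 121 in DESeq2, 28 without the nSyb libraries and 225 with the replicate number as a block.

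In prolongata females (10 and 10 libraries) Scr was higher in the foreleg by 2.61 ± 0.20 and Ubx lower by -4.06 ± 0.48. The proximal leg genes tsh and tio were higher by 0.50 ± 0.08 and 0.62 ± 0.10, and dsx was 0.36 ± 0.13 (adjusted p = 0.31, edgeR). Hox genes (3 rose and 1 fell of 11 in either adjustment, with a median of -0.01; adjusted p = 2.8e-04 by camera, direction up) and tracheal genes (1 rose of 11, 5 adjusted over the list alone; adjusted p = 1.4e-07 by camera) each had adjusted p = 0.036 with an estimated correlation. The female comparison called 69 genes, 33 higher and 36 lower. It called 139 in DESeq2, 33 without the nSyb libraries, 106 with the stage score and 414 with the replicate number as a block.

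**Figure D3:**
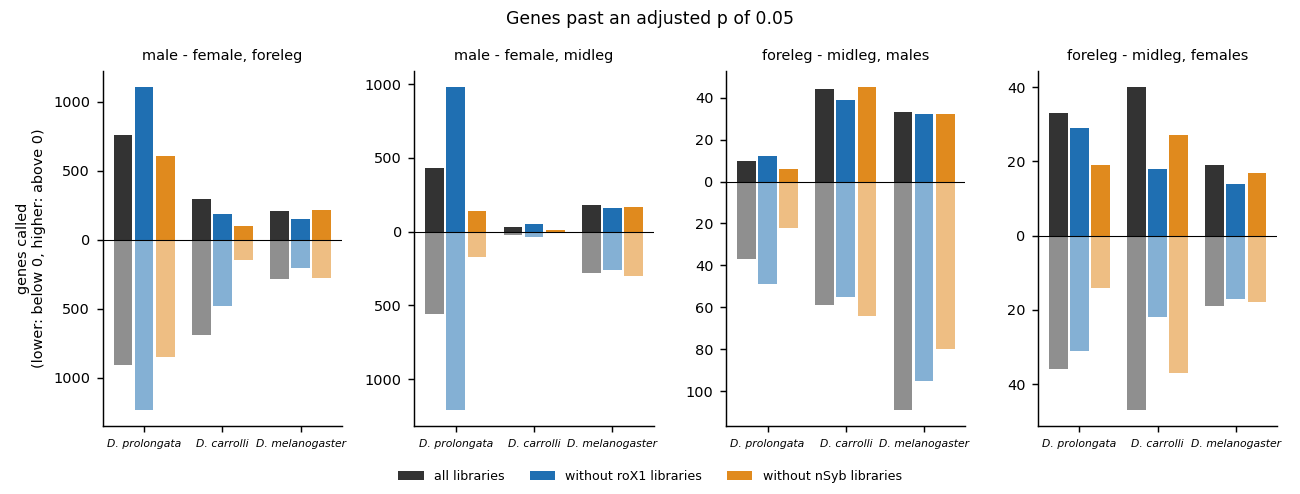
Genes past an adjusted p of 0.05 in edgeR, those higher drawn above 0 and those lower below, for the sex comparisons in each leg and the leg comparisons in each sex, by species. Bars give the count with all libraries, without the libraries labelled female with high roX1 and without the libraries with high nSyb; in the carrolli foreleg the last count is 246 against 983.

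From early to late in prolongata (averaged over sex and leg) Scr rose by 0.83 ± 0.15, Antp by 0.84 ± 0.22, InR by 0.62 ± 0.10, dac by 0.61 ± 0.08 and Dll by 0.24 ± 0.06, together with CrebA, a regulator of secretory genes, at 0.68 ± 0.07. The Notch pathway inhibitor Brd changed by -0.70 ± 0.08 and tra by -0.24 ± 0.08, and dsx was 0.19 ± 0.10 (adjusted p = 0.12, edgeR). Of 31 Hedgehog, Wingless and Dpp genes 23 rose and 3 fell (adjusted p = 1.3e-08 by camera), of 20 adhesion genes 16 rose (17 adjusted over the list alone; 5.9e-09), of 23 axon guidance genes 18 rose (9.4e-09), of 25 proximodistal genes 17 rose (1.2e-06) and of 19 Notch and joint genes 14 rose (6.1e-05). The other counts were equal when adjusted over the list alone, and each list had adjusted p = 0.17 with an estimated correlation. Of 20 respiration genes 17 fell, also when adjusted over the list alone (adjusted p = 5.3e-10 by camera, and adjusted p = 0.17 with an estimated correlation). Of 18 muscle genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -1.36 (adjusted p = 0.0051 by camera, and adjusted p = 0.51 with an estimated correlation). A total of 5023 genes were called, 2432 higher and 2591 lower late. Stage coincides with library serial number, so stage and any effect of that order cannot be told apart.

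Late minus early called 5028 genes in carrolli (2266 higher, 2762 lower) and 3987 in melanogaster (1954 higher, 2033 lower). InR rose by 0.55 ± 0.11 and 0.29 ± 0.09, dac by 0.32 ± 0.06 and 0.24 ± 0.07, Dll by 0.21 ± 0.04 and 0.23 ± 0.05, and Antp by 0.86 ± 0.20 and 0.46 ± 0.13. The mitotic kinase gene aurA fell in carrolli (-0.34 ± 0.05) and the replication gene PCNA in melanogaster (-0.33 ± 0.04). Of 41 cell cycle genes 20 fell and 6 rose in carrolli (22 and 6 adjusted over the list alone) and 15 fell and 2 rose in melanogaster (17 and 5), with adjusted p = 0.0056 and 0.0017 by camera. They had adjusted p = 0.40 and 0.52 with an estimated correlation. Called in the same direction in all 3 species were 1021 higher and 1044 lower genes, against 103 and 117 expected of independent lists among 8008 genes tested in each. roX1 in carrolli was -0.26 ± 0.96 (adjusted p = 0.85) and became 2.29 without the library labelled female midleg early replicate 1 (adjusted p = 0.041). Ubx in melanogaster was 0.14 ± 0.40 (adjusted p = 0.82) and became -0.66 without male foreleg late replicate 2 (adjusted p = 0.023, edgeR in each case).

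In carrolli, whose male forelegs are not enlarged, dsx was lower in male than female forelegs by -1.15 ± 0.10, at 20.9 ± 2.31 CPM (n = 10) against 46.2 ± 4.26 CPM (n = 10), and Sxl by -1.30 ± 0.13. roX1 (5.18 ± 1.53), roX2 (5.48 ± 1.10) and msl-3, a further gene of the dosage compensation complex (0.19 ± 0.04), were higher, roX1 by 8.73 without female foreleg early replicate 1. tra (-0.04 ± 0.10), Scr (0.09 ± 0.14), InR (-0.23 ± 0.14), dac (-0.09 ± 0.09) and Dll (-0.06 ± 0.06) did not pass. Of 23 axon guidance and neuronal genes 6 fell and 0 rose (12 and 0 adjusted over the list alone), with adjusted p = 1.9e-06 by camera, and adjusted p = 0.80 with an estimated correlation. Named after their values were seen, the synaptic genes nSyb, Syt1 and brp were lower by -2.68 ± 0.61, -2.48 ± 0.61 and -3.42 ± 0.75, and VGlut, the vesicular glutamate transporter, by -4.98 ± 1.12. nSyb reached 61.4 and 40.7 CPM in 2 female forelegs and at most 2.77 CPM in any male foreleg. Of 18 muscle genes 0 were called in edgeR, and 0 adjusted over the list alone, with a median of 0.86 (adjusted p = 1.1e-04 by camera, and adjusted p = 0.80 with an estimated correlation). The comparison called 983 genes, 294 higher and 689 lower. The balance turned with the replicate number as a block, where 472 were higher and 310 lower and 464 were shared with the 983. It called 508 without female foreleg early replicate 1, 333 without female foreleg late replicate 4, and 246 (98 higher, 148 lower) without the nSyb libraries, of which 237 were shared with the 983.

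In carrolli midlegs dsx was lower in males by -1.11 ± 0.12 (n = 7 and 10), Sxl by -1.21 ± 0.14 and msl-3 higher by 0.19 ± 0.04. roX1 was 3.6 ± 1.47 (adjusted p = 0.43, edgeR) and roX2 3.82 ± 1.05 (0.099), with the male-level library labelled female midleg early replicate 1 among the females, and Scr was -0.25 ± 0.16 (0.60). Of 13 sex determination genes 1 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.96 by camera). The comparison called 54 genes, 29 higher and 25 lower. It called 141 without the library labelled female midleg early replicate 1, 89 without female foreleg early replicate 4, 86 without male foreleg early replicate 1, 22 without the unnumbered male midleg early library, 88 without the roX1 libraries and 20 without the nSyb libraries. The interaction called 0 genes in edgeR and 0 in DESeq2, with 249 at an unadjusted p under 0.05. There dsx was -0.04 ± 0.15 and Scr 0.34 ± 0.22.

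In melanogaster forelegs (9 male and 8 female libraries) dsx was lower in males by -0.91 ± 0.11, at 53.0 ± 13.7 against 97.6 ± 11.6 CPM, Sxl by -0.94 ± 0.08 and tra by -0.72 ± 0.08. msl-2 was higher by 1.26 ± 0.04, roX1 by 6.30 ± 0.72 and roX2 by 6.78 ± 0.90 (10.49 without female foreleg late replicate 6). Scr was 0.11 ± 0.21 (adjusted p = 0.79, edgeR) and InR 0.00 ± 0.13 (1.00). Of 14 sex determination genes 5 rose and 3 fell, the counts adjusted over the list alone being equal, with adjusted p = 6.2e-04 by camera, and adjusted p = 0.17 with an estimated correlation. In midlegs (9 and 9 libraries) the counts were again 5 and 3 in either adjustment, with adjusted p = 3.4e-05 by camera, and adjusted p = 0.042 with an estimated correlation. There dsx changed by -0.97 ± 0.10, tra by -0.80 ± 0.08, Sxl by -0.94 ± 0.08 and msl-2 by 1.29 ± 0.04. Of 18 antimicrobial peptide genes 2 fell in forelegs (13 adjusted over the list alone), with a median of -2.04 (adjusted p = 6.2e-04 by camera, and adjusted p = 0.99 with an estimated correlation). The foreleg comparison called 498 genes (210 higher, 288 lower) and the midleg comparison 467 (184 higher, 283 lower), and 114 higher and 196 lower genes were called in both legs. With the replicate number as a block the counts were 888 and 875, and with the stage score the midleg count was 755.

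In melanogaster the interaction called 1 gene, CG4267, at -1.37 ± 0.24 (adjusted p = 0.047, edgeR), with 366 genes at an unadjusted p under 0.05 and 37 called in DESeq2. CG4267 was at 2.98 ± 1.00 CPM in male forelegs and 6.01 ± 1.12 CPM in female forelegs, against 6.65 ± 3.00 and 5.13 ± 1.80 CPM in midlegs. The call was kept only without female foreleg early replicate 6, female midleg late replicate 5, male foreleg late replicate 3 or male midleg late replicate 6, and the count was 0 without any other of the 35 libraries. It was also 0 without the roX1 libraries and without the nSyb libraries.

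Scr and Ubx also differed between the legs of the other species. In carrolli Scr was higher in the foreleg by 3.77 ± 0.19 in males and 3.43 ± 0.16 in females, Ubx lower by -4.60 ± 0.64 and -3.05 ± 0.56, vg by -2.21 ± 0.26 and -2.01 ± 0.24, and the tarsal gene ss by -1.49 ± 0.28 and -1.66 ± 0.26. In melanogaster Scr was higher by 2.97 ± 0.22 in males and 2.64 ± 0.22 in females, Ubx lower by -2.66 ± 0.59 and -3.59 ± 0.65, and tio higher by 0.43 ± 0.06 in each sex. The male Ubx value became -4.25 without male foreleg late replicate 2, which held 21.6 CPM of Ubx. Of 12 Hox genes in carrolli 3 rose and 1 fell in each sex in either adjustment, with adjusted p = 0.0046 in males and 1.1e-05 in females by camera, and adjusted p = 0.23 and 0.032 with an estimated correlation. Of 11 in melanogaster 3 rose and 1 fell in each sex (5 and 2 in males and 3 and 1 in females adjusted over the list alone), with adjusted p = 3.7e-06 and 6.7e-06 by camera, and adjusted p = 0.083 and 0.11 with an estimated correlation. Camera gave the direction up for each of these 4 Hox tests, while the list medians were -0.20 and -0.08 in carrolli males and females, 0.43 in melanogaster males and -0.13 in melanogaster females. In melanogaster females 0 of 15 haemocyte genes were called (9 fell when adjusted over the list alone; median -0.80), with adjusted p = 6.8e-13 by camera, and adjusted p = 0.16 with an estimated correlation.

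The leg comparisons called 103 genes in carrolli males (68 without male midleg early replicate 5), 87 in carrolli females (40 without the roX1 libraries), 142 in melanogaster males (91 without male foreleg early replicate 3) and 38 in melanogaster females. With the replicate number as a block they called 162 in carrolli females, 822 in melanogaster males and 198 in melanogaster females. In all 6 leg comparisons of the 3 species, 5 genes were higher in the foreleg (Scr, tio, CG8483, natalisin and lncRNA:CR45559) and 3 were lower (Ubx, the cuticle gene Cpr78Ca and the cell surface gene beat-IIIc). The last-named noncoding RNA and both lower genes other than Ubx were named after their values were seen. lncRNA:CR45559 was higher in male forelegs by 4.65 ± 0.58 in prolongata, 6.31 ± 0.59 in carrolli and 3.55 ± 0.27 in melanogaster.

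The 3 species were last compared directly, to ask where the foreleg sex difference of prolongata departed from that of its relatives. In the joint fit dsx differed by -1.35 ± 0.14 (adjusted p = 8.5e-11, edgeR). The male to female difference in its counts was thus larger in prolongata than the mean of the other species. Each species was counted against its own gene list, and whether differences in gene annotation contribute was not tested. Scr differed by -1.07 ± 0.23 (0.00083), Doc2 by -0.86 ± 0.12 (7.3e-07) and Diap1 by -0.69 ± 0.11 (1.4e-05). tra (-0.34 ± 0.12, adjusted p = 0.058), InR (-0.47 ± 0.17, 0.059), dac (-0.31 ± 0.12, 0.081), Antp (0.76 ± 0.32, 0.11) and Dll (-0.06 ± 0.08, 0.74) did not pass. The proneural gene sc was at 12.1 ± 4.74 CPM in male and 31.3 ± 8.81 CPM in female prolongata forelegs, and at 28.8 and 33.6 CPM in carrolli and 30.0 and 34.2 CPM in melanogaster in the same order.

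By groups, the male to female change was lower in prolongata than the mean of the other species for 13 of 31 Hedgehog, Wingless and Dpp genes and higher for 0 (15 and 0 adjusted over the list alone), with adjusted p = 3.4e-08 by camera, and adjusted p = 0.34 with an estimated correlation. It was higher for 6 of 19 respiration genes and lower for 0, also when adjusted over the list alone (adjusted p = 6.2e-06 by camera, and adjusted p = 0.45 with an estimated correlation). It was lower for 7 of 26 neural precursor genes (9 adjusted over the list alone), 7 of 25 proximodistal genes (8 lower and 2 higher adjusted over the list alone) and 4 of 19 Hippo genes (6 adjusted over the list alone). Their adjusted p was 0.0018, 0.0018 and 0.0019 by camera, and adjusted p = 0.34, 0.45 and 0.45 with an estimated correlation. The difference was called for 1045 of 9501 genes, 435 higher and 610 lower in prolongata. It was called for 1153 without the roX1 libraries and 987 without the nSyb libraries, which in carrolli female forelegs carry the neuronal genes described above. The replicate number as a block gave 2069.

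The interaction of sex and leg differed between prolongata and the other species for 1 gene, Obp49a, an odorant-binding protein gene named after its value was seen (8.91 ± 1.79, adjusted p = 0.032, edgeR), with 208 genes at an unadjusted p under 0.05 and 12 called in DESeq2. Its level was at most 0.970 CPM in any female library of prolongata and rested on single libraries, with maxima of 8.21 CPM in prolongata male forelegs, 11.1 CPM in carrolli female forelegs and 41.7 CPM in carrolli male midlegs. dsx (-0.17 ± 0.21) and Scr (-0.05 ± 0.34) did not pass. No gene was called without prolongata female foreleg early replicates 2 or 4, female midleg early replicate 2, female midleg late replicates 1 or 4, male foreleg early replicate 1, male foreleg late replicate 5, male midleg early replicate 3 or male midleg late replicate 5, or without carrolli female foreleg early replicate 4, male midleg early replicate 4 or male midleg late replicate 3. The count was 2 without prolongata female midleg early replicate 1, male midleg early replicate 1 or male midleg late replicates 1, 3 or 4, without carrolli female midleg early replicate 4, or without melanogaster female foreleg late replicate 6, female midleg late replicates 4 or 5, male foreleg early replicate 2 or male midleg late replicate 3. It was 0 without the roX1 libraries and 0 without the nSyb libraries.

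Across species, 12 genes were higher and 47 lower in male forelegs of all 3, against 0.249 and 1.65 expected of independent lists. Among the 12 were roX1, roX2, ssx, a paralogue of Sxl (0.31 ± 0.06, 0.26 ± 0.06 and 0.56 ± 0.03 in prolongata, carrolli and melanogaster), and the respiratory complex gene ND-18 (0.51 ± 0.09, 0.49 ± 0.10 and 0.35 ± 0.08). In midlegs 2 genes were higher and 11 lower in males of all 3 species, the 11 including dsx, Sxl and Fs. Pairwise in the foreleg, prolongata and carrolli shared 92 higher and 99 lower genes (18.9 and 57.4 expected), prolongata and melanogaster 22 and 79 (8.80 and 22.9 expected), and carrolli and melanogaster 33 and 69 (3.82 and 17.6 expected).

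X-linked genes were counted among the called genes by their position in D. melanogaster, which 80.7% of tested prolongata, 87.6% of carrolli and 98.1% of melanogaster genes had. In melanogaster forelegs 89.2% of genes lower in males and 48.1% of genes higher in males were X-linked, against 16.5% of genes tested. In prolongata forelegs the shares were 28.9% and 18.3% (16.7% of genes tested), and in carrolli forelegs 34.4% and 28.4% (16.6%). Fisher's exact test for genes higher in males gave odds ratios of 1.13 in prolongata (adjusted p = 0.25), 2.05 in carrolli (1.5e-06) and 4.92 in melanogaster (2.1e-26), adjusted over 12 tests. In midlegs the odds ratios were 1.5 (adjusted p = 0.0026), 21.4 (1.5e-12) and 5.06 (2.6e-24) in the same order, with 22.8% of higher genes on the X in prolongata. Genes lower in male forelegs gave 2.22 (4.8e-19), 2.93 (1.3e-29) and 49.0 (2.7e-168). The median log2 change of X-linked genes in male forelegs was -0.08 in prolongata, -0.07 in carrolli and -0.08 in melanogaster, against -0.00, 0.02 and 0.02 for autosomal genes.

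**Figure D4:**
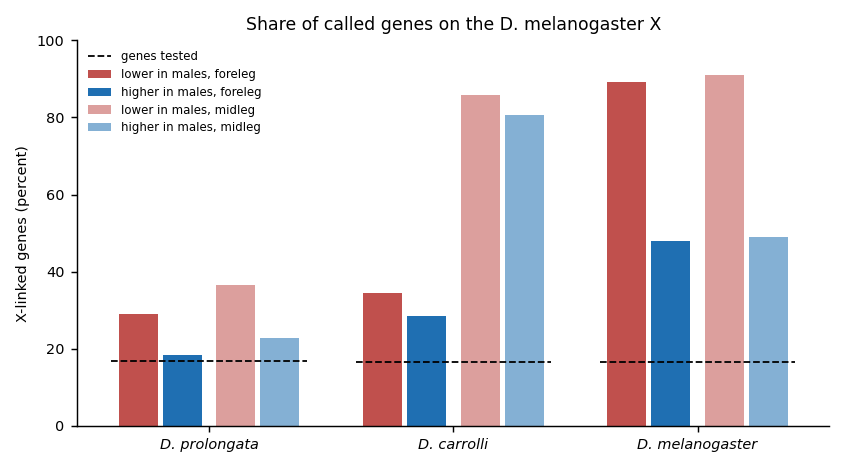
Share of called genes that lie on the D. melanogaster X chromosome, in percent, for genes lower or higher in males in each leg and species (bars), with the share among genes tested (dashed lines, 16.5% to 16.7%). The share lower in male forelegs is 89.2% in melanogaster, 34.4% in carrolli and 28.9% in prolongata.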

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

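The tests of male RNA and of wrong or swapped labels, the counts and changes without the nSyb libraries and the count with the stage score were chosen only after the results they concern had been seen. The test of the carrolli genes in a melanogaster library was written before its result.

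The first pattern is roX1 in libraries labelled female. In prolongata it stood apart from its group at 78.0 CPM in female foreleg early replicate 1 (the others 0.0730 to 0.183), 449 CPM in female foreleg late replicate 1 (0.108 to 52.3), 85.2 CPM in female midleg early replicate 3 (0.162 to 12.5) and 557 CPM in female midleg late replicate 1 (0.123 to 27.8); the libraries at 449 and 557 CPM also held 1249 and 1984 CPM of the haemocyte gene Hml, above the 529 CPM reached in any other prolongata library, male ones included. Over the 12 libraries above 5% of their male mean, the share of roX2 divided by the share of roX1 had a median of 0.864 (range 0.378 to 1.28), which is consistent with RNA from male larvae in the pool, from discs or another tissue, and 11 of the 12 lay below 50% of the male mean, which argues against a wrong label for these. In the twelfth, the carrolli library labelled female midleg early replicate 1, 74 genes called between the sexes in forelegs had a median position of 0.978 (quartiles 0.763 to 1.32) between the female mean (0) and the male mean (1). A wrong sex label would give this, but so could neuronal genes raised in other females, such as replicate 2 (21.1 CPM of nSyb). More directly, dsx was 18.0 and Sxl 122 CPM in the library. The male midleg early libraries held 14.2 to 19.5 and 93.2 to 134 CPM, and the other female ones 31.1 to 38.8 and 202 to 352 CPM. These levels are those of a wrong sex label. As 0 of 17 carrolli libraries labelled male lay below 5% of the male mean, a swap with one of these is argued against, while male samples not analysed here were not checked and no biological explanation was tested.

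The second pattern is the set of genes lower in male forelegs of carrolli, 689 genes led by neuronal ones (310 were lower with the replicate number as a block). A candidate explanation is RNA from nervous tissue left on some female discs, since central nervous tissue lies near the leg discs and nSyb, Syt1 and brp moved together. In melanogaster male foreleg early replicate 4, another species and sex with nSyb at 49.3 CPM, where the same genes should then be raised, 590 of them lay a median log2 of 2.16 above the other libraries of the group (quartiles 0.21 to 3.08), against -0.02 for all genes. Without the nSyb libraries 148 genes were lower, 146 of them among the 689, and the median log2 change of the 594 still tested went from -2.11 (median SE 0.57) to -0.64 (0.32), against 0.25 and 0.24 for the 294 higher genes. Per gene the change without them was a median of 0.433 of that with all libraries (quartiles 0.285 to 0.997), and 2 of the 594 changed sign, so with quartiles this wide a lower level in every male library cannot be told apart from nervous tissue for the set as a whole, and a sex difference stays open.

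The third pattern is the sex difference of the prolongata foreleg (1662 genes), in which 14 of 31 Hedgehog, Wingless and Dpp genes fell and 10 of 20 respiration genes rose (adjusted p = 0.30 each with an estimated correlation), while with stage 23 of the 31 rose and 17 of the 20 fell (adjusted p = 0.17 each with an estimated correlation). A difference in developmental age between the sexes could give such a pattern. With the stage score as a covariate the count was 2802. A covariate can raise a count by taking up spread within groups, so the count does not bear on age. The list medians moved from -0.24 to -0.22 for Hedgehog, Wingless and Dpp genes and from 0.26 to 0.24 for respiration. The score as measured thus accounted for little of these medians. The stage score did not pass between the sexes in any of 12 exact permutation tests (lowest adjusted p = 0.524), which does not show that it was equal. With 3 to 5 libraries per sex a difference in a single group could not have passed after adjustment over the 12 tests. In prolongata the male minus female score was -0.19 in early and -0.06 in late forelegs, and 0.25 in early and -0.20 in late midlegs. In male forelegs the score's genes that are higher late had a median log2 change of -0.08, and those lower late 0.04. Younger males would give these directions. In midlegs the medians were -0.004 and -0.03. Without the nSyb libraries the count was 1456, of which 1343 were shared with the 1662, which argues against nervous tissue as the whole source. A biological difference between male and female discs stays open as a hypothesis, as does a difference in developmental age. Other tissues such as muscle and differences in how the sexes were collected also stay open and were not tested.

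Other levels stood apart from their group in Dixon's test, which flags about 1 in 20 groups by chance; 11 of 87 tested combinations of gene and group did. In prolongata female midleg late replicate 1, dsx was 37.8 CPM (the others 72.4 to 77.8) and Ubx 12.4 CPM (21.9 to 24.5). Scr was 265 CPM in prolongata female foreleg late replicate 1 (503 to 599), and both of these libraries are those with high roX1 and Hml given above. Scr was 469 CPM in melanogaster male foreleg late replicate 4 (257 to 291). InR was 44.5 CPM in prolongata female midleg early replicate 3 (26.2 to 29.5). Ubx was 8.03 CPM in carrolli female foreleg late replicate 5 (0.0265 to 1.98) and 21.6 CPM in melanogaster male foreleg late replicate 2 (0.199 to 1.07), where Scr was 291 CPM.

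Differences between groups that passed their own test were the species difference of the foreleg sex contrast (1045 genes), with dsx at -1.35, Scr at -1.07, Doc2 at -0.86 and Diap1 at -0.69. The melanogaster interaction called 1 gene, CG4267 at -1.37, and the species difference of the interaction called 1, Obp49a.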

How the results depend on the processing

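The leave-outs by roX1 and nSyb and the stage score were chosen after seeing the data; the other settings were fixed before the data were examined. Values outside 1.5 times the reported count follow, and the cause was not tested except where fewer genes or libraries by construction give it. DESeq2 called, in prolongata, 121 genes between male legs, 139 between female legs, 8 in the interaction, 464 in late forelegs and 7 in the stage difference; in carrolli, 128 between sexes in midlegs and 147 between female legs; in melanogaster, 307 and 81 between male and female legs and 37 in the interaction; and 12 in the species difference of the interaction. Without a low-count filter the prolongata late foreleg count was 98. The melanogaster interaction count was 0 with that setting, with RLE, with unstranded counts, without roX1 libraries and without nSyb libraries.

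Without the roX1 libraries prolongata gave 2190 genes in midlegs, 1279 in early and 785 in late forelegs, and carrolli 88 in midlegs and 40 between female legs. Without the nSyb libraries prolongata gave 315 in midlegs, 28 and 33 between male and female legs and 383 in early forelegs, and carrolli 246 in forelegs and 20 in midlegs. The species difference of the interaction was 0 under each of these leave-outs. With the stage score prolongata gave 2802 in forelegs, 2082 in midlegs, 106 between female legs, 1604 early and 695 late, carrolli 139 in midlegs, and melanogaster 755 in midlegs and 216 between male legs. The list tests passed 4 times with an estimated correlation and 92 times with fry.

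The labels do not say that libraries with the same replicate number are paired. Legs with the same number correlated above 0.1 in 14 of 17 prolongata, 12 of 15 carrolli and 13 of 15 melanogaster pairs. A library correlated best with its own number in 25 of 34, 21 of 30 and 23 of 30 cases. The median correlation was 0.342, 0.296 and 0.271, against -0.103, -0.091 and -0.062 for legs with other numbers. Leg contrasts without a block may thus ignore a pairing. Between the sexes the median for the same number was 0.113, -0.030 and 0.127. The block joined the legs of the same sex in leg contrasts and libraries of both sexes in sex contrasts. With the replicate number as a block prolongata gave 3195 genes in forelegs, 2495 in midlegs, 2203 early, 1081 late, 225 and 414 between male and female legs and 1 in the interaction. In carrolli forelegs the block turned the balance of directions, with 472 genes higher and 310 lower (782 called, 464 shared with the 983) against 294 and 689. Higher and lower calls also shifted in prolongata late forelegs (487 and 594), carrolli midlegs (116 and 163) and melanogaster male (376 and 446) and female legs (76 and 122). Carrolli gave 279 in midlegs and 162 between female legs, and melanogaster 888 in forelegs, 875 in midlegs, 822 and 198 between male and female legs and 0 in the interaction. The species difference gave 2069, and 0 in its interaction.

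Leaving out 1 library at a time gave, in prolongata, 436 to 1619 in midlegs, 22 to 63 between male legs, 338 to 911 early and 54 to 458 late; in carrolli, 333 to 1472 in forelegs, 22 to 141 in midlegs and 68 to 119 between male legs; in melanogaster, 91 to 169 between male legs and 0 to 1 in the interaction; and 0 to 2 in the species difference of the interaction. The prolongata foreleg count stayed between 1266 and 2042, the species difference between 827 and 1407, and the prolongata and carrolli interactions and the stage difference at 0 in edgeR. Among values of named genes, 12012 kept their side of the threshold without 1 library, and 168 lost and 59 gained a call. A further 34 passed in neither fit but changed sign by at least 1 standard error, and 2 changed sign with a call in at least 1 fit. Values called in both fits with the same sign are among the 12012 however far they moved. An example is roX1 in the prolongata foreleg sex contrast, at 5.30 with all libraries and 8.70 without female foreleg early replicate 1. Over those fits, roX1 in carrolli late minus early ran from -0.47 to 2.29, the highest without the library labelled female midleg early replicate 1, and Ubx in melanogaster late minus early from -0.66 to 0.29, the lowest without male foreleg late replicate 2. No setting varied the depth, which was 33297387 gene reads or more per library; levels near 1 CPM, such as Ubx in forelegs and Obp49a, rest on few reads.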

Other observations

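The splits and the tests of X-linked genes were written before their results; the genes named in the first paragraph were chosen after their values were seen.

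Several genes outside the main account differed between the sexes in every species. The activin antagonist Fs was lower in male forelegs by -3.81 ± 0.34 in prolongata, -1.93 ± 0.15 in carrolli and -1.31 ± 0.24 in melanogaster, and the prolongata change exceeded the mean of the others by -2.18 ± 0.30 (adjusted p = 4.3e-07, edgeR). DIP-alpha, an immunoglobulin cell surface protein gene, was lower by -2.55 ± 0.42, -1.26 ± 0.22 and -0.75 ± 0.12, with a species difference of -1.55 ± 0.35 (adjusted p = 0.0012, edgeR). CG10702 was lower by -3.44 ± 0.24 and -2.80 ± 0.23 in prolongata and carrolli and by -0.47 ± 0.13 in melanogaster. Higher in males were CG9782 (1.60 ± 0.21, 1.28 ± 0.17 and 0.47 ± 0.07) and CG14615 (2.33 ± 0.51, 2.62 ± 0.45 and 0.49 ± 0.13). The histone methyltransferase gene Su(var)3-9 was higher by 0.23, 0.25 and 0.32 and the mitochondrial import gene Tom20 by 0.31, 0.30 and 0.21.

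Markers of larval tissues outside the disc varied widely between the libraries of each species. The fat body storage protein gene Lsp1beta ranged from 37.7 to 2665 CPM in prolongata, 65.5 to 2585 CPM in carrolli and 158 to 12924 CPM in melanogaster. The haemocyte gene Hml ranged from 19.6 to 1984, 18.1 to 318 and 33.7 to 279 CPM, and the muscle gene Mhc from 8.43 to 1956, 9.12 to 478 and 14.6 to 1092 CPM.

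The hypothesis that X-linked genes are over-represented among genes higher in males of the foreleg was tested in each species. The odds ratio was 4.92 in melanogaster (Fisher's exact p = 8.9e-27), 2.05 in carrolli (1.2e-06) and 1.13 in prolongata (0.25), so it held in the first 2 species and was not shown in prolongata forelegs. In prolongata midlegs the odds ratio was 1.5 (Fisher's exact p = 0.0024). Genes lower in male forelegs gave larger odds ratios, 49.0 in melanogaster (4.4e-169), 2.93 in carrolli (3.3e-30) and 2.22 in prolongata (2.8e-19), so X linkage was not particular to genes higher in males. Whether the species differ in X linkage was not tested, and 80.7% of prolongata genes had a chromosome. In carrolli the lower genes are the 689 that include neuronal genes, of which 146 stayed called without the nSyb libraries. Their X share without those libraries was not tested.

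Other splits of the same libraries by sex, leg or stage were drawn, 100 for each contrast with the real one included. The splits moved libraries independently, while legs with the same replicate number correlated. They can therefore argue against chance but not exclude it. In prolongata only the real split called as many genes, which argues against chance, for the sex comparison in forelegs (1662 against at most 2 in another split), midlegs (992 against 39), early forelegs (745 against 15) and late forelegs (174 against 1), and for stage (5023 against 120). The same held in carrolli for male legs (103 against 1) and stage (5028 against 1834), and in melanogaster for forelegs (498 against 2), female legs (38 against 10) and stage (3987 against 1097). In the joint fit 1 of 40 splits, the real one, called 1045 genes, against at most 23.

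For some contrasts the splits were close, and the genes shared with comparisons of other libraries are given beside them. In carrolli forelegs (983 against 982), carrolli midlegs (54 against 31) and melanogaster midlegs (467 against 448) only the real split called as many. Of the carrolli midleg genes 29 higher and 24 lower were also called in the foreleg (0.852 and 1.72 expected of independent lists), of the melanogaster midleg genes 114 and 196 (3.61 and 7.61), and of the carrolli foreleg genes 92 and 99 in prolongata forelegs (18.9 and 57.4). In male legs 2 of 100 splits called as many (47 against 89 in prolongata, 142 against 213 in melanogaster), while these species shared 6 genes higher and 10 lower in the foreleg (0.0338 and 0.287 expected). For female legs 6 of 100 splits called as many in prolongata (69 against up to 1282) and 13 in carrolli (87 against up to 1972), so the splits do not exclude chance for these counts, but 10 higher and 9 lower genes were shared with male legs in prolongata (0.0303 and 0.122 expected) and 29 and 34 in carrolli (0.176 and 0.277). These overlaps do not exclude chance, because genes that vary together between libraries raise them above those of independent lists. Legs with the same replicate number also correlated, with medians of 0.342, 0.296 and 0.271 in prolongata, carrolli and melanogaster. A library effect can therefore recur in both legs. For these 7 contrasts only the shares of splits given above bear on chance.

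For the melanogaster interaction 2 of 100 splits called as many (1 against up to 97), but its 1 call was lost in 31 of 35 fits without 1 library, so chance is not taken as excluded. For the species difference of the interaction 24 of 40 splits called as many (1 against up to 538), and chance cannot be excluded. The prolongata and carrolli interactions and the prolongata stage difference called 0, which all 100 splits match by construction (highest 19, 1710 and 308), so the splits decide nothing there. Splits that call several times the real count, as for the female legs of prolongata and carrolli and both of the interactions with 1 call, point to a structure of the samples that the groups do not describe. In the carrolli foreleg and the melanogaster midleg another split came close to the real count, which points the same way.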
